A study of Homo sapiens with 6 samples.

How the data were processed

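Chromatin accessibility was measured by ATAC-seq in 6 libraries of MCF7 cells, a human breast cancer cell line that expresses the oestrogen receptor. ATAC-seq uses the Tn5 transposase to insert adapters into open chromatin, so that regions with many inserted fragments appear as peaks. The labels divide the libraries into 2 groups of 3, dormant cancer cells (DCCs) and A-DCCs, an abbreviation that the labels do not spell out. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates came from separate cultures, so p-values over libraries measure only the spread between these libraries, which may be technical. P-values of tests over genes, such as those on identifier numbers, describe these lists and do not measure that spread.

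Per the labels' protocol, nuclei were isolated, treated with Tn5 and amplified by PCR, and the libraries were cleaned with beads. Per the submitters' processing notes, BWA, MACS2 and the hg18 build were used. Tool versions, MACS2 thresholds, read filters, the handling of the Tn5 offset, the annotation release and the rule that ties a peak to a gene are not given in the sources used here. The authors deposited 1 list per library of Ensembl gene identifiers for genes that had a peak, with 1 identifier per line and no value beside it. The lists hold no repeated identifier. They give presence or absence only: peak number, height, position and significance are not known for any gene. Read depth is also unknown, so no counting interval or detection limit can be given for a gene that a list leaves out. Absence from a list can come from closed chromatin, from shallow sequencing or from a peak just under the caller's threshold.

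The reference gene table used here, which has 59792 genes, pairs 0 of them with an Ensembl identifier. The identifiers were therefore used exactly as deposited, without symbols, gene types or positions. As a result, the 37 gene lists and the 26 single genes chosen by symbol before the data were examined could not be looked up, and the 2 planned results on those lists (enrichment among genes of one group, and share of each list with a peak) were not computed. The rule for named genes had the same need. In its place, the 2 lowest-numbered identifiers of each group's set are printed, a choice made after the data were seen.

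The 6 lists were joined into a presence table of 38917 genes listed in at least 1 library. Group differences in list length were tested with an exact permutation test over the 20 labellings of the 6 libraries, two-sided, for which the smallest possible p is 0.1. A gene was called A-DCC-only when all 3 A-DCC libraries and no DCC library listed it, and DCC-only in the opposite case. The similarity of lists was measured by the Jaccard index (shared genes over genes in either list) for all 15 pairs of libraries, and the mean within groups was set against the mean between groups over the 10 splits of the libraries into 3 against 3, one-sided, again with a smallest possible p of 0.1. The counts were also compared with 1000 presence tables randomised by exchanging genes between pairs of libraries, which keeps how many libraries list each gene and how many genes each library lists. Such tables show what these totals give when genes are otherwise placed in libraries at random. Lists cut at different depths from one fixed ranking would instead be nested, each shorter list lying within each longer one. Genes are not replicates, so this comparison describes these libraries. In simulated tables with 200 genes planted per direction, the A-DCC-only count exceeded its randomised mean by 185.8 among 37668 genes and the DCC-only count by 186.9. With no planted genes the excesses were 15.8 and -0.7 among 37613 genes.

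Alternatives were the omission of each library, looser criteria for a group-only gene (at least 2 libraries, or at least 2 more libraries than the other group), the phi correlation in place of the Jaccard index, and the replicate number as a block. These, the tests described above (with the comparison of the group-only counts with other splits and with randomised tables) and the groups were fixed before the data were examined. The stored size of each list, which tracks its number of identifiers, was known by then, so the test of list length was not chosen blind to it. The criterion of at least 1 library, the ratio of the sets, the comparison of agreement within each group, the analyses of 2 against 2 libraries and those of identifier numbers were added afterwards. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3 were used.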

Results

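To compare accessible chromatin in dormant cancer cells with that in A-DCCs, ATAC-seq profiles of MCF7 cells were examined as lists of the genes that had a peak, with 3 libraries per group. The series title speaks of awakening dormant cells, and the labels give no further detail on how either population was obtained. Together the libraries listed 38917 genes, of which 16658 (42.8%) had a peak in all 6. This common set was the largest class. A further 5455 genes were listed by 1 library alone.

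The first comparison asked whether the groups differed in how many genes had accessible chromatin. DCC libraries listed 26141 ± 3232 genes and A-DCC libraries 28898 ± 796 genes (mean ± SD, n = 3 each), a difference of 2758 genes. The groups overlapped: DCC replicate 3 listed 28839 genes, more than the 28030 of A-DCC replicate 1. The difference did not stand out from the spread between libraries (p = 0.2, exact permutation test, two-sided). The smallest p this test allows is 0.1, so it could not have decided the question. DCC replicate 2 had the shortest list, with 22559 genes, and without it the difference was 967 genes. DCC replicate 1 listed 27024 genes, and A-DCC replicates 2 and 3 listed 29072 and 29593.

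**Figure D1:**
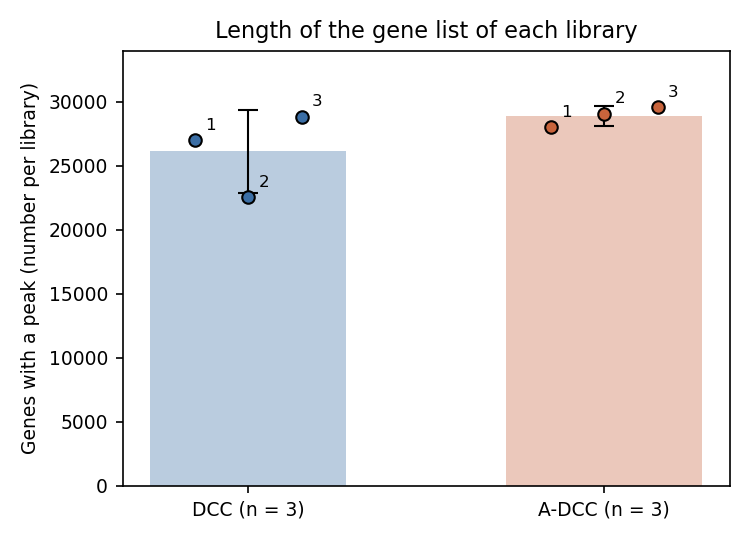
Number of genes with a peak (vertical axis) in the 3 DCC and the 3 A-DCC libraries. Points are libraries with their replicate numbers, bars are group means and error bars are the SD (n = 3); DCC replicate 2 is the lowest at 22559, and the other libraries lie between 27024 and 29593.

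The second comparison asked which genes were accessible in one population and not in the other. In all, 2411 genes (6.20% of the 38917) had a peak in every A-DCC library and in no DCC library. The opposite set was smaller, with 902 genes (2.32%) listed in every DCC library and in no A-DCC library. The lowest-numbered identifiers of the A-DCC-only set were ENSG00000003249 and ENSG00000004975, and those of the DCC-only set were ENSG00000006606 and ENSG00000013293. The files do not pair identifiers with gene names, so neither set is described by function here. Among the 9 other ways to divide the libraries into 3 against 3, the highest number of genes listed in all libraries on one side and none on the other was 221, in either direction. In the 1000 randomised tables with gene and library totals kept, the A-DCC-only set held 473 ± 20 genes (mean ± SD), with a highest value of 547, and the DCC-only set held 83.7 ± 9.1 genes, with a highest value of 112. The observed sets thus lay above those highest values, at 5.10 and 10.8 times the randomised means. No single gene can be called at 3 libraries against 3: the 3313 genes of both sets each had p = 0.1 in Fisher's exact test, two-sided, the smallest possible, and 0 of 38917 genes reached an unadjusted p under 0.05.

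The relative size of the 2 sets depended on how many libraries had to list a gene. The ratio of A-DCC-only to DCC-only genes was 2.67 with all 3 libraries required. When 2 libraries of a group sufficed, 3563 genes were listed in A-DCC and no DCC library and 2469 in DCC and no A-DCC library, a ratio of 1.44. When 1 library was enough, the order turned, with 5484 genes in the A-DCC set and 6003 in the DCC set, a ratio of 0.914. DCC replicate 2 also affected the ratio. Without it, 2698 genes were listed in the 3 A-DCC libraries and in neither remaining DCC library, and 1742 genes in both remaining DCC libraries and no A-DCC library, a ratio of 1.55.

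**Figure D2:**
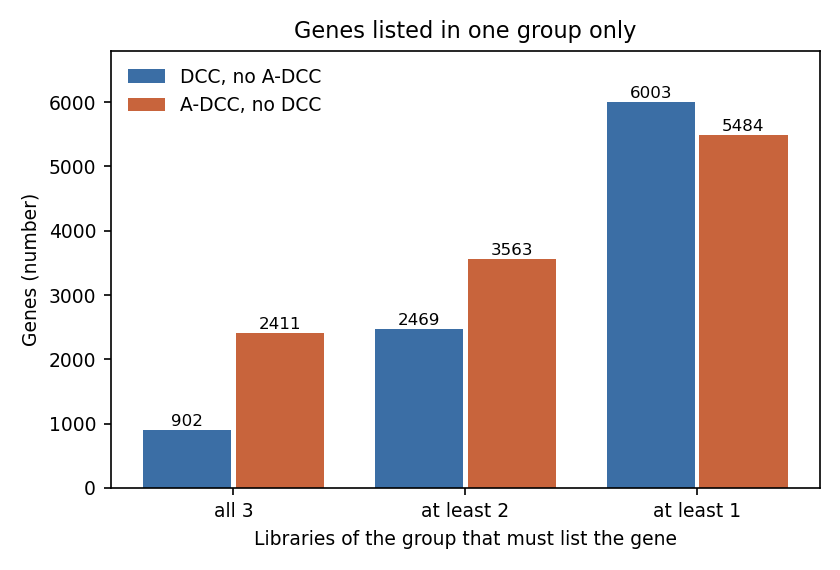
Number of genes (vertical axis) listed in one group and in no library of the other, for 3 criteria on how many libraries of the group must list the gene (horizontal axis). The A-DCC bar is the higher one with all 3 libraries required (2411 against 902) and the lower one when 1 library is enough (5484 against 6003); each bar is a single count with no error bar.

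Most genes with a peak in one population also had one in the other. By a consensus of at least 2 of 3 libraries, 25984 genes had a peak in DCCs and 28731 in A-DCCs, and 22197 genes were in both. The shared genes made up 85.4% of the DCC consensus and 77.3% of the A-DCC consensus. A-DCC consensus genes outside the DCC consensus numbered 6534, and DCC consensus genes outside the A-DCC consensus numbered 3787.

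The third comparison asked whether libraries of one population resembled each other more than libraries of the other population. The Jaccard index was 0.834 ± 0.005 among A-DCC libraries (mean ± SD over 3 pairs), 0.688 ± 0.048 among DCC libraries (3 pairs) and 0.642 ± 0.042 between the groups (9 pairs). Pairs share libraries and are not independent. The mean within groups, 0.761, exceeded that between groups by 0.119, the largest difference of the 10 splits of 3 against 3. The next largest was -0.010, but these differences sum to 0 over the 10 splits by construction, so the sign of the others is no separate evidence. The rank of the real split gave p = 0.1 in the exact permutation test, one-sided, the smallest that 10 splits allow. By the Jaccard index, the ranges of single pairs overlapped for DCC libraries: the DCC pairs with replicate 2 reached 0.655 and 0.666, below the highest value between groups, 0.679. By the phi correlation they did not overlap, with 0.432 to 0.483 for the DCC pairs and 0.210 to 0.329 between groups.

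Gene lists agreed less among DCC libraries than among A-DCC libraries. The 3 A-DCC libraries shared 25050 genes, 76.1% of the 32914 genes listed by at least 1 of them. The 3 DCC libraries shared 19005 genes, 56.9% of the 33433 listed by at least 1. The mean Jaccard index was 0.145 higher within A-DCC than within DCC. The largest such gap between the sides of any other split was 0.097 (p = 0.1, exact permutation test over the 10 splits, two-sided, the smallest possible). Each side of another split mixes pairs within and between groups, which dilutes such a gap. The rank of the real split is therefore no separate test of unequal agreement. Without DCC replicate 2 the gap was 0.090. The remaining DCC pair, replicates 1 and 3, had an index of 0.743, against 0.829 to 0.840 for the A-DCC pairs. DCC replicate 2 was the only library to lack 2973 genes that the other 5 listed, whereas each other library was the only one to lack 206 to 507 genes. DCC replicate 3 had the most genes listed by no other library, 1788, against 819 and 927 for the other DCC libraries and 488 to 756 for the A-DCC libraries.

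**Figure D3:**
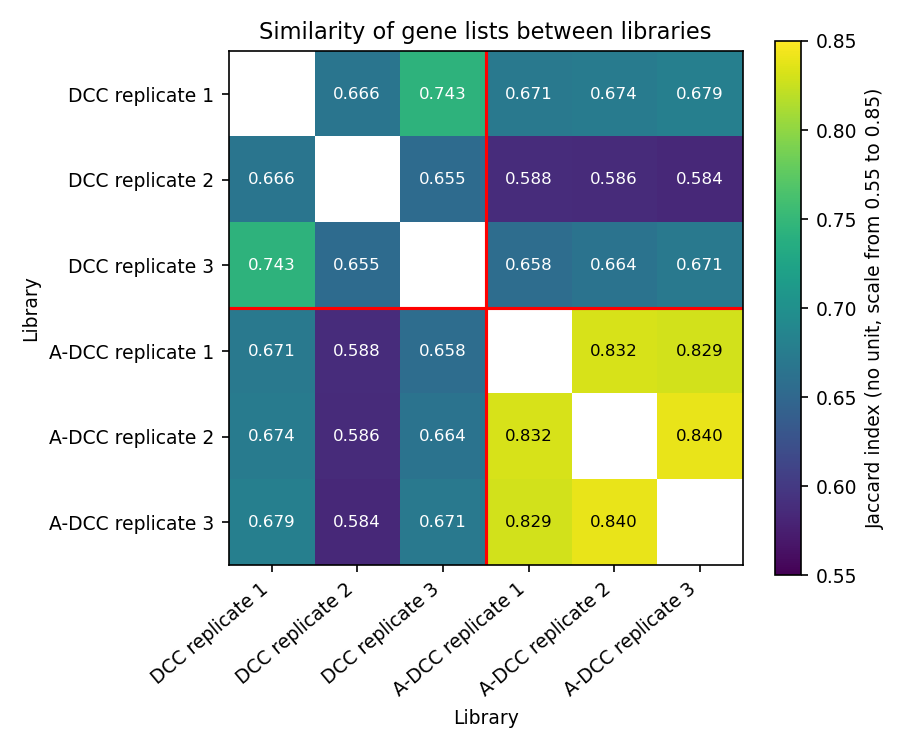
Jaccard index of the gene lists for each pair of the 6 libraries (rows and columns are libraries, colour and printed values give the index, red lines part the groups). The 3 A-DCC pairs lie between 0.829 and 0.840, the 3 DCC pairs between 0.655 and 0.743, and the 9 pairs between groups between 0.584 and 0.679.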

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

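The larger number of genes listed in A-DCCs kept its direction when each library was left out (differences of 967 to 4107 genes, permutation p from 0.1 to 0.4), and so did the higher similarity within groups (0.082 to 0.164 by the Jaccard index, and 0.288 by the phi correlation). The gap in agreement between the groups stayed positive too (0.090 to 0.178, and 0.188 by phi). The count of A-DCC-only genes was 2411. It rose to 5698 when at least 2 more A-DCC than DCC libraries had to list a gene, and to 5484 when 1 library sufficed; each omitted library left it within 1.5 times of its value. The count of DCC-only genes was 902 and went to 3009 with at least 2 more libraries, to 2469 with at least 2 libraries and none of the other group, to 6003 with 1 library, and to between 1013 and 1742 when a library was left out, with 1742 for DCC replicate 2 and 1394 for DCC replicate 1. Looser criteria and fewer libraries admit more genes by construction. The ratio of the sets, 2.67, ranged from 1.55 to 3.02 when a library was left out, was 1.44 with at least 2 libraries, and turned to 0.914 with 1 library. In 2 against 2 libraries, without DCC replicate 2 and without A-DCC replicate 1, 2 or 3, it was 1.65, 1.47 and 1.39.

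Libraries of the same number in the 2 groups did not deviate together (correlations of -0.004, 0.009 and 0.015), so the numbers were not taken as pairs, and not every library correlated best with its own number. With the replicate number as a block, the difference in list length was 2758 genes (exact sign-flip p = 0.25, the smallest possible). The blocked counts, 5698 and 3009 genes, equal those of at least 2 more libraries by construction, so they are no separate check. The alternatives limited to protein-coding genes and those of the planned gene lists were not run, since no gene type or symbol was at hand. Read depth is unknown and may differ between the libraries.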

Other observations

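The comparisons with other splits, and those of the group-only counts with randomised tables, were fixed before the data were examined, although what each explanation would give was set down only after the counts had been seen. The other tests below were chosen after seeing the data: those of identifier numbers, of the set ratio without DCC replicate 2 and with 1 library required, and those of library totals as a source of the set ratio, of the agreement gap and of the genes missing from DCC replicate 2, whose outcomes were still open when they were chosen. Ensembl numbers its identifiers in the order in which genes are added, so the number dates a gene's first annotation. Of the 16658 genes listed in all 6 libraries, 63.5% had a number at or below 224459, the median of all listed genes. The share was 34.2% of the 2411 A-DCC-only genes and 34.6% of the 902 DCC-only genes, close to the 32.6% of the genes listed by a single library. Other genes listed in exactly 3 libraries had 41.8%. Relative to these, the A-DCC-only share differed by -7.54 percentage points (Fisher's exact p = 1.4e-06, over genes, which are not replicates) and the DCC-only share by -7.17 (Fisher's exact p = 0.00041). With the upper quartile of the numbers as the divider, the A-DCC-only difference was -1.37 points (Fisher's exact p = 0.368) and the DCC-only difference -4.09 points (Fisher's exact p = 0.0364). With the lower quartile they were -6.56 and -7.84 points. A hypothesis that the A-DCC-only and DCC-only sets hold different kinds of genes, as dated by identifier, found no backing: the shares differed by -0.372 percentage points (95% interval -4.01 to 3.26, Fisher's exact p = 0.837), and by 1.28 and 2.72 points with the lower and upper quartile as dividers.

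Both group-only sets were larger than library totals with random placement give. Under such placement the sets would stay within the randomised range, but they lay at 5.10 and 10.8 times the randomised means. Nested lists, cut from one ranking at unequal depths, would hold neither set here. DCC replicate 3 (28839 genes) listed more than A-DCC replicate 1 (28030), and DCC replicate 2 (22559) listed the fewest. Chance in the grouping was not decided, because 10 splits allow no share under 0.05. The real split, the 1 with the most genes, had 2411 and 902, against a highest of 221 in the others. A gene of exactly 3 libraries counts in 1 split only, so the 3313 in the real split left 1614 for the others. For similarity the real split had 0.119 against a highest of -0.010, but those differences sum to 0 over the 10 splits by construction. Both contrasts therefore follow in part from the real values themselves. A difference between DCCs and A-DCCs stays open as an explanation. So does any difference in handling between the groups, since the labels give no preparation or sequencing batch.

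The excess of A-DCC-only over DCC-only genes was 2.67-fold. DCC replicate 2 alone is not the whole source, because the lowest ratio without it in 2 against 2 libraries was 1.39. When 1 library of a group was enough, the ratio was 0.914. It follows from how many genes at least 1 library of each group listed, 32914 in A-DCCs and 33433 in DCCs. This restates the poorer agreement among DCC lists and does not test it, so that agreement stays open as a source of the excess. List lengths stay open: randomised tables with these totals had a mean ratio of 5.72 (4.14 to 8.63), an imbalance in the same direction and larger than the observed one, but they hold no difference between the groups, so they do not show what these lengths give beside one. A wider accessible set in A-DCCs is neither shown nor excluded.

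The gap in agreement, 0.145 in the Jaccard index, exceeded the mean of the randomised tables by 0.108. Those tables place genes at random given the totals. For nested lists cut from one ranking, the index is the shorter length over the longer. The DCC lengths (22559 to 28839 genes) would then give a lower mean index than the A-DCC lengths (28030 to 29593). The excess over random placement therefore does not show that list length has a small part in the gap, and its share is not known. DCC replicates 1 and 3, with lists nearly as long as the A-DCC ones, still had a lower index than each A-DCC pair. DCC replicate 2 added to the poorer agreement among DCC lists. The 2973 genes that it alone lacked were 1.53 times the randomised mean of 1943. In nested lists cut from one ranking, every gene of exactly 5 libraries would be missing from the shortest list. The excess over random placement therefore does not argue against a shorter list as its source. Of the genes listed by the other 5 libraries DCC replicate 2 lacked 15.1%. Of the 1742 genes listed by both other DCC libraries and no A-DCC library it lacked 48.2%. A larger share in the second class was not particular to it. There DCC replicate 1 lacked 492 of 1394 genes and DCC replicate 3 lacked 235 of 1137. In the first class they lacked 507 and 366, beside the 16658 genes listed in all 6 libraries. More varied chromatin in DCCs and uneven library quality could each give the poorer agreement, and no value at hand separates them.

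The highest identifier number in the lists was 288588. Numbers in this range belong to Ensembl releases made for assemblies later than hg18, the build in the submitters' processing notes. The lists give no positions, so which build and annotation were used was not tested.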
